A study of Mus musculus with 3 samples.

How the data were processed

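Immune cells washed from the airspaces of mouse lungs (bronchoalveolar lavage fluid) were profiled by droplet single-cell RNA sequencing, per the labels' protocols with a 10x Genomics Chromium kit that reads transcripts from their poly(A) end and tags each molecule with a unique molecular identifier (UMI). Per the labels, C57BL/6J mice, 12 weeks old, breathed filtered air, 1 ppm ozone or 1.5 ppm ozone for 3 hours, and cells were collected 22 to 24 hours later. Cells of 3 to 4 mice per group were pooled before library construction, so each group is 1 library and the mice within a pool cannot be told apart. There is therefore no biological replicate and no test between groups: no p-value, standard error or count of significant genes is given.

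The deposited values are whole-number counts of UMIs per gene and cell barcode, made by the authors with Cell Ranger 8.0.0, per the file headers, and on the mouse genome build GRCm39 (mm39), per the submitters' processing notes. Whether intronic reads were counted is not given in the sources used here. The lowest UMI total of any deposited barcode was 500. The reference annotation at hand is of the earlier build GRCm38, so no coordinates are printed. That annotation was used, matched by Ensembl gene identifier, only for the genomic span and transcript length of genes, and 99.8% of the 4199 genes considered had a span. Gene names are those in the deposited tables.

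From the counts, barcodes with at least 300 genes, at least 500 UMIs and at most 10% of UMIs from mitochondrial genes were kept, which left 3479, 2241 and 6577 cells for filtered air, 1 ppm and 1.5 ppm. Scrublet, as implemented in scanpy 1.11.5, was run per library with a fixed seed and marked 2, 12 and 1 cells as doublets. At 0.12% of all cells these calls are too few to have worked, so doublets remain in the data. The remaining 12282 cells were scaled to 10000 UMIs, log transformed and reduced to 30 principal components of 2000 variable genes chosen per library and combined, leaving out mitochondrial, ribosomal protein and sex-linked genes. A graph of 15 nearest neighbours, weighted by shared neighbours, was divided by the Leiden method at resolution 1.0 into 20 clusters (leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3).

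Clusters took a class name only from marker genes fixed beforehand, and the name ends in "-like" for that reason. A marker counted for a cluster if at least 25% of its cells had a UMI and its level was at least 25% of that in the highest cluster of 30 or more cells. The class with the largest share of its markers counted, and at least 3 of them, gave the name. A cluster stayed unnamed if its cells had under 1/3 of the median UMIs of their own library with none of the class's markers among its 10 leading genes, or if those 10 genes held more markers of another class, at least 2 of them or one as the first gene. This scoring was set after the data were seen, while the markers were not. The alveolar-macrophage-like class took 12 clusters and 11094 cells. Cluster 0, led by Dnah11, Lepr and Rbfox1, was its largest cluster in the filtered air and 1 ppm libraries, and cluster 1, led by Il1b, Idi1 and Cyp51, in the 1.5 ppm library. The numbers of cells in the sub-clusters of this class are not compared, because genes that differ between libraries define them.

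For each library the UMIs of all alveolar-macrophage-like cells were summed and expressed as CPM, the share of that sum in parts per 1e6. Levels carry exact Poisson 95% intervals, ratios of 2 levels carry exact conditional intervals, and shares of cells carry exact binomial (Clopper-Pearson) 95% intervals. All of these cover counting error only, not differences between mice, days or library preparations. A log2 ratio is of CPM after adding 1 UMI to each sum. A gene was counted as differing in size at 2-fold or more, with at least 50 CPM in the higher library and at least 100 UMIs over the 3 libraries. The upper limit set by a count of 0 is that of 3 counts.

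The genes named in the text follow a rule of size fixed before the data were examined. It takes 12 genes higher and 12 lower in both ozone libraries, ranked by the smaller of both log2 ratios, then 5 higher and 5 lower for each ozone library against air, 8 higher and 8 lower for 1.5 ppm against 1 ppm, and up to 4 members of each gene list by absolute log2 ratio. Mitochondrial, ribosomal protein, sex-linked, haemoglobin and antigen receptor genes, predicted genes and markers of other cell classes were left out of the ranking. A gene below 5% of its level in another named class of at least 50 cells in the same library is named apart, since free RNA could bring it. Genes named for clusters outside the alveolar-macrophage-like class and for the background were chosen after their values were seen. In all, 21 gene lists were fixed. For each, the median log2 ratio of the members with at least 100 UMIs is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is no test. Intervals of list medians come from 200 Poisson redraws of the sums.

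Shares of cycling cells were taken after thinning each cell at random to 5000 UMIs, which left out 61, 34 and 314 shallower alveolar-macrophage-like cells of the air, 1 ppm and 1.5 ppm libraries. The interval formulas and the size rule were tested on simulated counts with 200 genes altered by known amounts. For 1.5 ppm against filtered air, on 3904 genes, all 50 genes raised 2.5-fold and 0 of 50 genes raised 1.5-fold passed the 2-fold rule, as did 0 of 3708 unaltered genes, and 95.6% of intervals of unaltered genes held the true ratio. Of 400 simulated lists of 20 unaltered genes in that comparison, 5.75% lay outside the middle 95% of random lists. The simulated libraries were drawn from 1 shared profile with counting error alone, without differences between pools, cells or preparations. These results therefore check the formulas and give no rate of false calls for the real libraries.

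The alternatives were a stricter cell filter (1000 genes, 2000 UMIs, 5% mitochondrial), a looser one (200 genes, no UMI minimum, 20% mitochondrial), doublets kept, Leiden resolutions 0.5 and 2.0, each library clustered alone, scaling by TMM factors (edgeR 4.0.16, R 4.3.3) or by median-of-ratios factors, the mean of each cell's CPM, thinned cells, cells without 3 or more G2 and M phase UMIs, subtraction of free RNA, other minimum levels, folds and added UMIs. Added after the data were seen were leaving out the cells in the top 5% of doublet scores of each library, cells of 2.5 to 4% mitochondrial UMIs, leaving out cluster 12, leaving out clusters 7 and 18, and log2 ratios centred on genes of like span or like transcript length in 20 bins. The free RNA profile was the sum of all cells of a library, and its share, 7.22%, 5.33% and 3.66% for air, 1 ppm and 1.5 ppm, was the 10th percentile of marker ratios; since alveolar macrophages supply most of that profile, the subtraction moves little.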

Results

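The data were UMI counts from 3 pools of airspace immune cells, for mice that breathed filtered air, 1 ppm ozone or 1.5 ppm ozone, a reactive gas that irritates the airways. The filtered air library held 5307 barcodes and 59359742 UMIs, the 1 ppm library 3233 barcodes and 42825676 UMIs, and the 1.5 ppm library 7269 barcodes and 95403078 UMIs. Median UMIs per barcode were 10551, 12507 and 11283, and median genes per barcode 3646, 3957 and 3818. The median mitochondrial share was 5.2%, 4.65% and 2.33%, and the filter at 10% removed 34.2%, 30.6% and 9.07% of barcodes for exceeding it, so it weighed most on the air and 1 ppm libraries. Each group was 1 pooled library, so there were no replicates, and all intervals cover counting error only.

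The first question was which cells the lavage held at each dose. Alveolar-macrophage-like cells, the resident phagocytes of the airspace, made up 95.2% of cells after filtered air (3311 of 3477, interval 94.5 to 95.9%), 95.2% after 1 ppm (2121 of 2229, 94.2 to 96.0%) and 86.1% after 1.5 ppm (5662 of 6576, 85.2 to 86.9%). Neutrophil-like cells, short-lived inflammatory granulocytes, numbered 1 in air (0.0288%, interval 0.000728 to 0.160%), 11 at 1 ppm (0.493%, 0.247 to 0.881%) and 79 at 1.5 ppm (1.20%, 0.952 to 1.50%). The class carried the calprotectin genes S100a8 and S100a9 at 12600 and 12840 CPM, with the chemokine receptor Cxcr2 at 1195 CPM. Migratory-dendritic-like cells, which carry antigen to lymph nodes and were led here by Ccl22 and Ccr7, were 0.777%, 0.673% and 0.806% of the libraries. Airway-epithelial-like cells were 0.661%, 0.852% and 0.836%, with overlapping intervals in both cases.

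Cells that stayed unnamed were 3.31% of the air library, 2.83% of the 1 ppm library and 11.1% of the 1.5 ppm library. Cluster 11 was led by the chemokine genes Ccl4 and Ccl3 and the matrix protein gene Thbs1. In air it had 0 of 3477 cells, with an exact upper limit of 0.106% and a limit of 3 counts of 0.0863%. It had 1 of 2229 cells at 1 ppm and 247 of 6576 at 1.5 ppm (3.76%, interval 3.31 to 4.24%). It carried S100a8 in 66.1% and Csf3r in 58.1% of its cells but too few fixed markers for a name, and nearly all of its cells came from 1 library. Its median mitochondrial share was 0.12%, against 0.13% in the neutrophil-like cluster, but Cxcr2 was found in 6.85% of its cells against 86.8% there. If its cells were counted with the neutrophil-like class, the 2 together made 0.0288%, 0.538% and 4.96% of the libraries. Cluster 14, with the T cell receptor complex genes Cd3g and Cd3e in 64.3% and 55.1% of its cells, was 0.575%, 0.269% and 1.09% of the libraries. Cluster 13, with the complement genes C1qa, C1qb and C1qc, was 1.35%, 1.08% and 1.48%. C1qa was found in 48.2% of its cells, and its best-matching class was conventional dendritic cell 1, with 5 markers counted. Cluster 19, with the club cell gene Scgb1a1 and the keratins Krt8 and Krt18, was 0.0575%, 0.135% and 0.669%. Its best-matching class was alveolar epithelial, with 6 markers counted, among them Hopx in 51.0% and Sftpa1 in 46.9% of its cells. Cluster 9, of few UMIs per cell (median 1056), was 1.32%, 1.30% and 4.06%. Its best-matching class was alveolar macrophage, with 7 markers counted and Chil3 in 96.8% of its cells, and the rule on low UMIs left it unnamed. Its 46, 29 and 267 cells are outside the alveolar-macrophage-like share, so part of the lower share at 1.5 ppm may be shallow macrophages. With a stricter cell filter the alveolar-macrophage-like share was 96.7%, 97.6% and 92.8%. No class other than the alveolar-macrophage-like had 100 cells in 2 libraries, so genes were compared in that class alone.

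**Figure D1:**
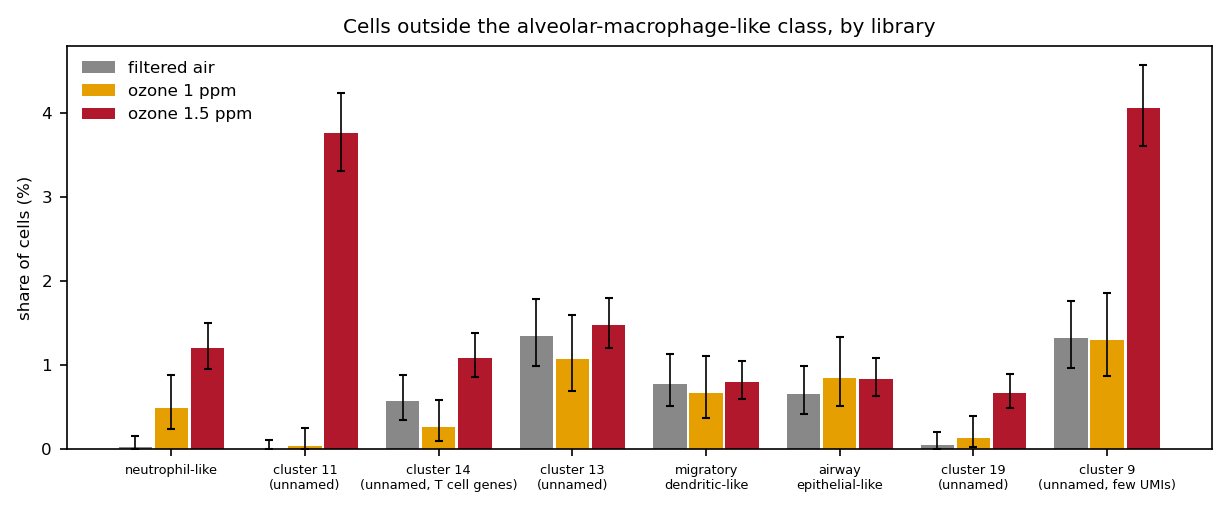
Share of cells (%) of each class or unnamed cluster outside the alveolar-macrophage-like class, as bars per library with exact binomial 95% intervals for counting error. Neutrophil-like cells were 0.0288% in air and 1.20% at 1.5 ppm, and cluster 11 was 3.76% at 1.5 ppm against 0 cells in air.

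The next comparison was how alveolar macrophages after 1 ppm ozone differed from those after filtered air. Few genes differed much in size. Of 4024 genes considered, 2 were at least 2-fold higher and 6 at least 2-fold lower after 1 ppm. Among the higher genes was Car4 (ENSMUSG00000000805), a membrane carbonic anhydrase and itself an alveolar macrophage marker. The lower genes were led by the metallothioneins Mt2 (ENSMUSG00000031762) and Mt1 (ENSMUSG00000031765), which bind metals, by the haem-degrading enzyme Hmox1 (ENSMUSG00000005413) and by the cystine importer Slc7a11 (ENSMUSG00000027737). Dusp6, a phosphatase of the ERK kinases, was also among the 6.

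Car4 stood at 180.5 CPM (interval 176.8 to 184.3) in air and 415.5 CPM (409.0 to 422.1) at 1 ppm, a ratio of 2.30 (2.24 to 2.36). Mt2 stood at 261.4 CPM against 54.5 CPM, a ratio of 0.209 (0.199 to 0.219), and Mt1 at 1293 CPM against 540 CPM, a ratio of 0.417 (0.411 to 0.424). Hmox1 had 394 CPM against 172 CPM, and Slc7a11 72.9 CPM against 23.1 CPM, with log2 ratios of -1.20 and -1.66. Cluster 12, whose leading genes include these 4, bears on the size: without it the log2 ratios were -1.98 for Mt2, -0.996 for Mt1, -0.37 for Hmox1 and -0.19 for Slc7a11. Dusp6 had a log2 ratio of -1.04. Wfdc17, a small secreted protein of macrophages, S100a6, a calcium-binding protein, and Colec12, a scavenger receptor, were 1.86-fold (1.75 to 1.98), 1.70-fold (1.60 to 1.81) and 1.77-fold (1.68 to 1.86) higher.

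Among the fixed lists at 1 ppm, cholesterol synthesis had 21 of 23 measured members above 0, with 3 at 1.5-fold or more (Fdps 0.72, Lss 0.65 and Sqle 0.62, enzymes on the path from mevalonate to lanosterol) and Pmvk at 0.57. Its median log2 ratio was 0.35, at percentile 100 of the random lists. Nuclear genes of oxidative phosphorylation had 23 of 23 members above 0 and a median of 0.34 (percentile 100), with Atp5j at 0.45 and Uqcrb at 0.43, none at 1.5-fold. Their median was 0.18 when centred on genes of like transcript length. Heat shock genes had 11 of 15 members below 0 and a median of -0.29 (percentile 0), with Hspa1b at -0.80 and Hsph1 at -0.45. The Nrf2 antioxidant list had 15 of 19 members below 0, 5 of them by 1.5-fold or more, and a median of -0.26 (percentile 0), with Me1 at -1.92 and Nqo1 at -1.20 at levels under 5 CPM; without cluster 12 that median was -0.015, and without cells holding 3 or more G2 and M phase UMIs -0.15 (percentile 7.88). Liver X receptor (LXR) targets had a median of 0.11 (percentile 98.2) with the apolipoprotein genes Apoc1 and Apoe at 1.21 and 0.97. That median was -0.025 (percentile 69.9) in cells of 2.5 to 4% mitochondrial UMIs and 0.08 (percentile 96.3) without cluster 12, but 0.21 (percentile 99.97) centred on genes of like span or like transcript length. The LXR list's sum was 2644 CPM in air and 2628 CPM at 1 ppm. Glycolysis had a median of 0.16 (percentile 99.9) with the glucose transporter gene Slc2a1 at 0.53.

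As measured, the other lists lay within the middle 95% of random lists at 1 ppm, some of them near its edge. The type I interferon list had a median of -0.18 (percentile 2.85) and 7 of 19 members at least 1.5-fold lower. Its leading members were scarce: Ifit1 had 62 UMIs in air and 2 at 1 ppm, a ratio of 0.0430 (0.00509 to 0.162), and the chemokine gene Cxcl10 had 308 and 21 UMIs, a ratio of 0.0908 (0.0554 to 0.141). Immediate early genes had a median of -0.17 (percentile 3.02), with 2 of 15 at least 1.5-fold lower, Fosb at -1.02 and Jun at -0.73. The list lay outside in all 8 alternatives for which percentiles were computed (0 to 1.60, medians from -0.32 to -0.16), and the interferon list in 5 of them (0.37 to 1.46). Metal and iron handling had 1 of 12 members higher and 5 lower by 1.5-fold, a median of -0.16 (percentile 7.59), the transporter Slc11a1 at -1.65 and the iron exporter Slc40a1 at -1.49, or -0.97 without cluster 12 and -0.81 without cells holding 3 or more G2 and M phase UMIs. The higher member was the siderophore-binding gene Lcn2 at 2.22, of 5 UMIs in air and 20 at 1 ppm. The list's sum was 23780 CPM in air and 26620 CPM at 1 ppm. Inflammatory cytokines had 2 of 17 higher and 2 lower, a median of 0.03 (percentile 80.2), and Cxcl3 at -2.19, Cxcl2 at -1.38 and Il1b at 1.26.

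Matrix and repair genes at 1 ppm had 3 of 18 members higher and 2 lower by 1.5-fold and a median of 0.06 (percentile 92.0), with the protease inhibitor gene Timp1 at 2.09 (9 and 31 UMIs), the elastase Mmp12 at -0.91 and the matrix gene Fn1 1.83-fold higher (1.79 to 1.87). Alternative activation, with 10 members, had a median of -0.02 (percentile 59.3), Chil4 at -0.45 and Chil3 at 0.33; its Ccl17, 2.06, was of 30 and 96 UMIs. S phase (20 members, Mcm2 at -0.27 and Rrm2 at -0.26) and G2 and M phase (22, Kif23 at -0.36 and Kif11 at -0.31) had medians of -0.08 (percentile 25.7) and -0.07 (percentile 33.2), with none at 1.5-fold. Lysosome and autophagy (20, Cd68 at 0.45 and Cd63 at 0.42) had a median of 0.05 (percentile 94.6). Lipid uptake and storage (19, Hilpda at 0.52 and Msr1 at 0.41) had -0.001 (percentile 78.4). Class II presentation (11, H2-Oa at -0.37 and H2-DMb2 at 0.35) had 0.007 (percentile 78.2).

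Complement and efferocytosis at 1 ppm (8 members, Mfge8 at 0.53 and Itgav at -0.24) had a median of 0.09 (percentile 89.1). The unfolded protein response (16, 1 of them at 1.5-fold higher, Trib3 at 0.72 and Herpud1 at -0.45) had -0.04 (percentile 63.9). The p53 targets (15, 1 of them lower, Plk2 at -2.17 and Gdf15 at -0.41) had -0.08 (percentile 31.5), and the mitochondrial genome (13, mt-Nd4 at -0.27 and mt-Nd3 at -0.20) had -0.03 (percentile 51.7).

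Alternatives also put other lists outside the middle 95% of random lists at 1 ppm. Centred on genes of like span, the unfolded protein response had a median of -0.15 (percentile 0), the mitochondrial genome -0.18 (percentile 0), S phase -0.08 (percentile 1.89) and p53 targets -0.10 (percentile 2.11). Centred on genes of like transcript length, complement and efferocytosis had 0.20 (percentile 99.0) and the mitochondrial genome -0.19 (percentile 0). By the mean of each cell's CPM, S phase had -0.20 (percentile 0.01) and G2 and M phase -0.14 (percentile 1.00). Without cells holding 3 or more G2 and M phase UMIs, S phase had -0.18 (percentile 0.24), G2 and M phase, which defined those cells, -0.47 (percentile 0) and metal and iron handling -0.23 (percentile 0.76). With the stricter cell filter, metal and iron handling had -0.32 (percentile 0.04).

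At 1.5 ppm the difference from filtered air was broader. Alveolar-macrophage-like cells had higher levels of cell cycle, cholesterol synthesis and heat shock genes, and lower levels of LXR targets and of most genes of the mitochondrial genome. Of 4159 genes considered, 60 were at least 2-fold higher and 14 at least 2-fold lower. The histone genes H2ac24, H1f5 and H1f4 led the higher genes at 6.90-fold (6.36 to 7.49), 6.07-fold (5.73 to 6.43) and 5.24-fold (4.83 to 5.68), with the replication factor gene Pclaf at 3.13-fold (3.02 to 3.25). Mt2, with a log2 ratio of -2.13, Mt1 with -1.46, the splicing regulator Rbfox1 with -1.74, the peroxisomal thiolase Acaa1b with -1.62 and the cell polarity scaffold Patj with -1.30 led the lower genes. Without cells holding 3 or more G2 and M phase UMIs, 33 genes were higher and 10 lower. Histone genes have close copies, so the values of single histone genes are uncertain.

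Cell cycle genes were higher throughout. All 22 G2 and M phase members stood above 0, 20 of them at 1.5-fold or more, with a median log2 ratio of 1.02 (percentile 100). The proliferation marker Mki67 stood at 60.5 CPM in air and 183 CPM at 1.5 ppm, a ratio of 3.02 (2.91 to 3.14), the survivin gene Birc5 had a log2 ratio of 1.49, Prc1, of the dividing spindle, 1.39 and Hmmr 1.38. In cells of 2.5 to 4% mitochondrial UMIs the median was 0.57, and without cells holding 3 or more UMIs of the list it was 0.28. All 20 S phase members were above 0, 15 at 1.5-fold or more, with a median of 0.67 (percentile 100) and the replication genes Cdc6 at 1.14 and Gins2 at 1.11, and a median of 0.20 without those cells. After thinning, 22.3% of cells (1191 of 5348, interval 21.2 to 23.4%) held 3 or more G2 and M phase UMIs at 1.5 ppm, against 8.98% (8.02 to 10.0%) in air and 7.57% (6.47 to 8.79%) at 1 ppm. Unthinned shares were 34.2%, 21.1% and 18.4%. The list made 1374 CPM at 1.5 ppm, 623 CPM in air and 582 CPM at 1 ppm. Neutrophil-like cells, which do not divide, reached 3 such UMIs in 4.40% of 91 cells (1.21 to 10.9%), unthinned, at a median of 2389 UMIs. Cluster 11 did so in 0.806% of 248 cells and airway-epithelial-like cells in 8.25% of 97 (3.63 to 15.6%) at a median of 1311 UMIs. These shares were not taken at the depth of the thinned macrophages. By level, the list made 193 CPM in neutrophil-like cells, 152 CPM in cluster 11 and 403 CPM in airway-epithelial-like cells, below the macrophages of each library.

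Cholesterol synthesis genes were higher in 23 of 23 measured members, 18 of them by 1.5-fold or more, with a median of 0.83 (percentile 100). Idi1 and Fdps, of the isoprenoid steps, had log2 ratios of 1.44 and 1.41, and the sterol enzymes Sqle and Cyp51 1.39 and 1.33. LXR targets, a mixed list that includes sterol exporters, were below 0 in 9 of 11 members, with a median of -0.48 (percentile 0), Pltp at -1.15, Mylip at -0.91 and the transporters Abca1 and Abcg1 at -0.82 and -0.69. Lipid uptake and storage had a median of -0.27 (percentile 2.15) with members both ways: the fatty acid translocase Cd36 at 0.501-fold (0.490 to 0.513), lipoprotein lipase Lpl at a log2 ratio of -0.87 and Pdk4 at -1.07, but the fatty acid binding protein Fabp5 at 1.19, and 3 members at least 1.5-fold higher against 5 lower. That list did not stay outside the middle 95% of random lists without cluster 12 (percentile 11.7), in cells of 2.5 to 4% mitochondrial UMIs (percentile 9.23) or centred on genes of like transcript length (percentile 2.97). Heat shock genes were above 0 in 15 of 15 members, 9 by 1.5-fold or more, with a median of 0.79 (percentile 100), Cacybp and Dnaja1 at 1.15 each and Hsph1 at 1.05. The unfolded protein response had a median of 0.19 (percentile 98.3), with Creld2 at 1.53, Manf at 1.47 and Sdf2l1 at 1.37, all of the endoplasmic reticulum, but Asns, for asparagine synthesis, at -1.06; its percentile was 92.2 centred on genes of like span and 96.4 by the mean of each cell's CPM.

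The mitochondrial genome list had a median of -0.69 (percentile 0), with 9 of 13 members at least 1.5-fold lower and 2 higher, among them mt-Nd3 at -1.39, mt-Cytb at -1.02 and mt-Co3 at -0.88, while mt-Nd6 stood at 1.02. The median mitochondrial share of alveolar-macrophage-like cells was 4.12%, 3.97% and 2.31% in air, 1 ppm and 1.5 ppm, and in cells of 2.5 to 4% mitochondrial UMIs the list median was -0.08 by construction. Nuclear oxidative phosphorylation genes had 22 of 23 members above 0, 4 at 1.5-fold or more, and a median of 0.36 (percentile 100), with Ndufb9 at 0.86 and Cox4i1 at 0.72. Centred on genes of like transcript length, that median was 0.06 (percentile 93.6). The type I interferon list had 5 of 19 members at least 1.5-fold lower and a median of -0.23 (percentile 0.75), with Ifit2 at -1.23 and Irf7 at -1.13, and it was 0.13 without cells holding 3 or more G2 and M phase UMIs and -0.005 without cluster 12.

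As measured, the remaining lists lay within the middle 95% of random lists at 1.5 ppm. Nrf2 antioxidant had 1 of 19 members higher and 5 lower by 1.5-fold and a median of -0.17 (percentile 22.8), with Hmox1 at -1.11, Me1 at -1.05 and Txn1 at 0.85. Without cluster 12 that median was -0.015 (percentile 80.8) and Hmox1 stood at -0.50. Metal and iron handling had 3 of 12 higher and 5 lower and a median of -0.18 (percentile 12.6), with Lcn2 at 2.92 (81 UMIs at 1.5 ppm), Mt2 at -2.13 and Slc40a1 at -1.41 (-0.90 without cluster 12). Its median was 0.21 (percentile 92.7) without cluster 12 and 0.01 without cells holding 3 or more G2 and M phase UMIs. By sum this list was higher after ozone, at 23780 CPM in air, 26620 CPM at 1 ppm and 36070 CPM at 1.5 ppm, with the ferritin gene Fth1 alone at up to 24010 CPM. Inflammatory cytokines had 3 of 17 higher and 1 lower, a median of 0.04 (percentile 71.0), and the monocyte chemokine gene Ccl2 at 2.13 (10 UMIs in air and 86 at 1.5 ppm), Il1b at 2.04, Ccl9 at -0.74 and Ccl3 at 0.60. Alternative activation had 2 of 10 higher, a median of -0.24 (percentile 8.19), with Pdcd1lg2 at 0.71 and Mrc1 at -0.40, and Ccl17 at 3.09, a gene of migratory-dendritic-like cells (1799 CPM there). Immediate early genes had 1 of 15 lower, a median of -0.10 (percentile 34.9), and Fosb at -0.90.

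Class II presentation at 1.5 ppm had 1 of 11 members higher and 1 lower by 1.5-fold and a median of 0.13 (percentile 91.3), with its regulator Ciita at 1.10 and H2-Oa at -1.20. Complement and efferocytosis had 1 of 8 higher and a median of -0.25 (percentile 9.43), with Mfge8 at 0.67 and the engulfment receptor Mertk at -0.50. Matrix and repair had 4 of 18 higher and 1 lower and a median of 0.002 (percentile 72.5), with Timp1 at 3.07 (9 and 151 UMIs), Spp1 at 1.34, Areg at 1.15 and Pdgfb at -0.84. The p53 targets had 2 of 15 higher and 1 lower and a median of 0.09 (percentile 90.8), with Bax at 0.91, Plk2 at -0.90 and Cdkn1a at 0.75. Glycolysis had 2 of 16 higher and a median of 0.10 (percentile 95.5), with Slc2a1 at 0.89 and Eno1 at 0.66, and lysosome and autophagy none of 20 and a median of -0.19 (percentile 15.4), with Hexa at -0.54 and Map1lc3b at 0.53. Centred on genes of like span, lysosome and autophagy had a median of -0.20 (percentile 0.36) and immediate early genes -0.31 (percentile 0.04), outside that range.

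**Figure D2:**
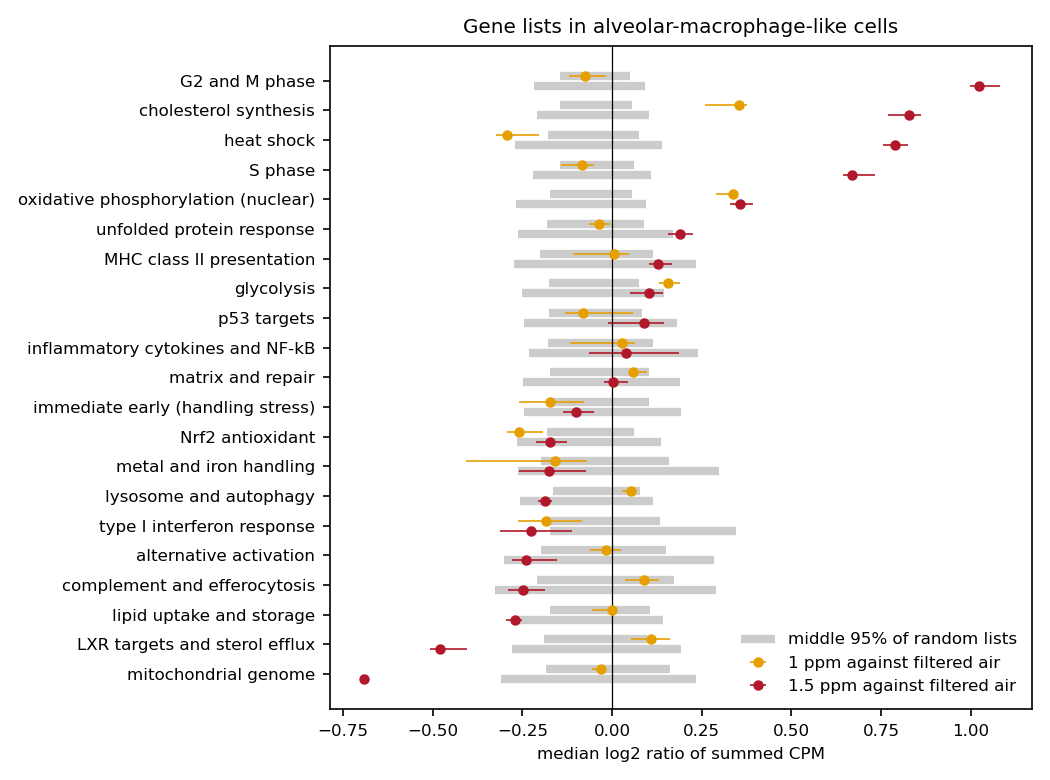
Median log2 ratio of summed CPM in alveolar-macrophage-like cells for each gene list, at 1 ppm (orange) and 1.5 ppm (red) against filtered air, with bars from Poisson redraws of the sums and grey bands for the middle 95% of random lists. The G2 and M phase list stands at 1.02 at 1.5 ppm and at -0.07 at 1 ppm, and heat shock at 0.79 and -0.29.

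Genes that differed from filtered air the same way at both doses were fewer. Lower in both were Mt2, Mt1, Hmox1, Dusp6 and Slc7a11, then the tight junction scaffold Patj, the toxin receptor Antxr2, the leptin receptor Lepr, the guidance factor Sema3e, Acaa1b, Phlda1 and Bckdhb, of branched-chain amino acid breakdown. Their log2 ratios ran from -2.26 for Mt2 to -0.68 for Bckdhb at 1 ppm, and from -2.13 for Mt2 to -0.69 for Phlda1 at 1.5 ppm. Without cluster 12 Slc7a11 was higher at 1.5 ppm, with a log2 ratio of 0.44. Higher in both were Car4, Wfdc17, Spp1, which encodes osteopontin, Fdps, H2ac24, the inflammasome adaptor Pycard, S100a6, Pmvk, the collagen-degrading protease Ctsk, the translocon subunit Ssr4 and the oxidative stress protein Park7. Spp1 stood at 232 CPM in air, 388 CPM (381.2 to 393.9) at 1 ppm and 587 CPM (582.0 to 592.1) at 1.5 ppm, and Ctsk at 338, 500 and 502 CPM.

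Il1b, the interleukin-1 beta gene, stood at 12.3, 29.4 and 50.5 CPM, a ratio of 2.40 (2.17 to 2.65) at 1 ppm and 4.12 (3.78 to 4.49) at 1.5 ppm. It is set apart because neutrophil-like cells of the 1.5 ppm library carried it at 2015 CPM and free RNA could bring part of it. S100a8 and S100a9, at 12600 and 12840 CPM in neutrophil-like cells, made 15.8 and 1.62 CPM in the macrophage sums of that library. These values argue against free neutrophil RNA as the main source of Il1b there, and Il1b also led cluster 1 of the alveolar-macrophage-like class. Among the list members named above, the same rule sets apart Lcn2, Cxcl2, Ccl3 and Ccl17, whose levels were 0.391 to 1.14% of those in another class. List members not named for their ratios also fell below it: Cp, Ccl4, Ifit3, H2-Eb1, Cd86, Egr1, Ier3 and Gadd45a. All of these genes stay in the list medians. Of the genes at least 2-fold higher, 2 were so at both doses, and of those at least 2-fold lower, 4 were. Without cluster 12 the lower genes shared were 2, Mt2 and Dusp6. Both ratios share 1 air library, with its mice and its counting error, so an unusual air pool would give such an overlap by itself.

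**Figure D3:**
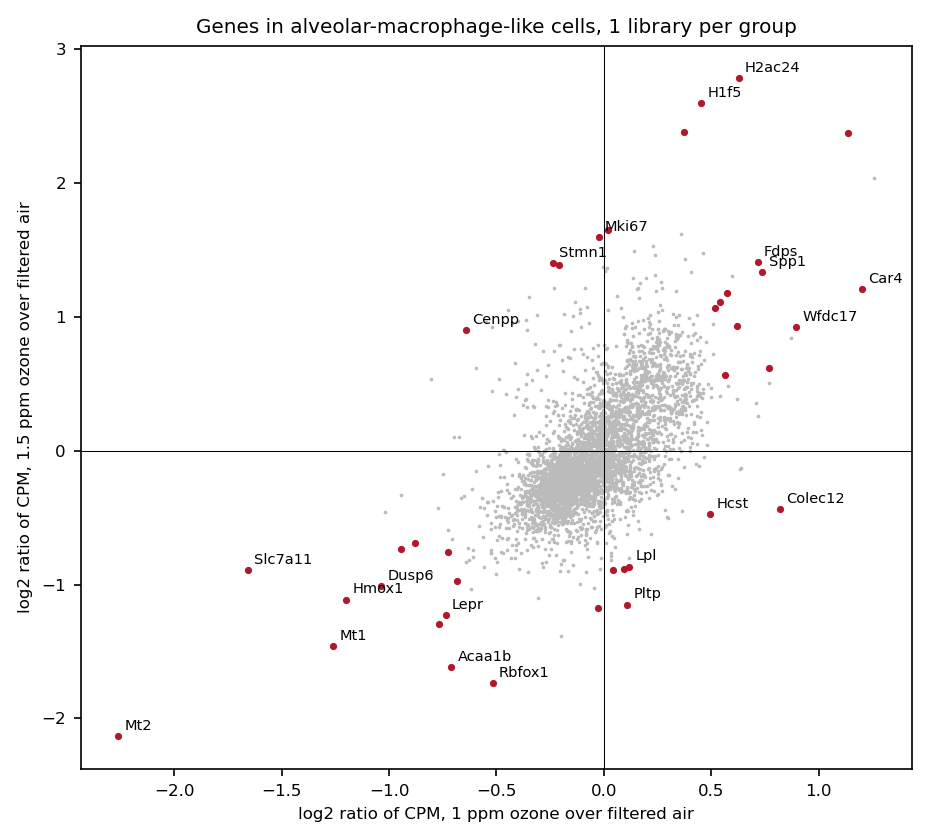
Log2 ratio of CPM in alveolar-macrophage-like cells at 1 ppm (horizontal) and at 1.5 ppm (vertical) against filtered air, 1 point per gene for 4199 genes, with the 39 genes of the naming rule in red. Mt2 lies at -2.26 and -2.13, and H2ac24 at 0.63 and 2.78.

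The last comparison was between the ozone doses. At 1.5 ppm 53 genes were at least 2-fold higher than at 1 ppm and 4 at least 2-fold lower, of 4055 considered. H2ac24, H1f5 and H1f4 were 4.46-fold (4.14 to 4.82), 4.43-fold (4.19 to 4.69) and 4.05-fold (3.73 to 4.40) higher, and the microtubule regulator Stmn1, Pclaf, Mki67, Prc1 and the kinetochore gene Cenpp had log2 ratios from 1.64 to 1.55. Lower at 1.5 ppm were Pltp (-1.26), Colec12 (-1.25), Rbfox1 (-1.22), the dynein gene Dnah11 (-1.15) and Lpl (-0.98), followed by the ganglioside enzyme B4galnt1, the signalling adaptor Hcst and Crip1. Lpl stood at 2525 CPM (2509 to 2542) at 1 ppm and 1277 CPM (1269 to 1284) at 1.5 ppm. Without cells holding 3 or more G2 and M phase UMIs, 24 genes were higher and 5 lower.

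By list, G2 and M phase had a median of 1.15 and S phase of 0.82 between the doses, heat shock of 0.92 with Hsph1 and Dnaja1 at 1.50 each, and cholesterol synthesis of 0.51 with Idi1 at 1.06 and Cyp51 at 0.93, all at percentile 100. LXR targets had all 11 members below 0 and a median of -0.69, and the mitochondrial genome a median of -0.66, both at percentile 0. In cells of 2.5 to 4% mitochondrial UMIs the G2 and M phase median was 0.72, that of cholesterol synthesis 0.31 and that of the mitochondrial genome, by construction, -0.17. Without cells holding 3 or more G2 and M phase UMIs, the median of G2 and M phase, which defined those cells, was 0.67 and that of S phase 0.305. Lysosome and autophagy had a median of -0.19 (percentile 0.42), with Ctsa at -0.80, and the unfolded protein response one of 0.22 (percentile 99.7), with Asns at -1.42 and Sdf2l1 at 1.38.

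Other lists passed the middle 95% of random lists between the doses only in part of the alternatives. Lipid uptake and storage had a median of -0.20 (percentile 0.70), with Pdk4 at -1.11, and percentile 4.85 in cells of 2.5 to 4% mitochondrial UMIs. Complement and efferocytosis had -0.23 (percentile 2.21), with C3 at -0.47, but lay inside in 6 of 8 alternatives: -0.12 (percentile 17.1) in those cells, -0.10 (percentile 12.3) without cells holding 3 or more G2 and M phase UMIs, and percentiles of 3.58 to 4.33 centred on like span or transcript length, with the stricter filter and by the mean of each cell's CPM. Without cells holding 3 or more G2 and M phase UMIs Nrf2 antioxidant had 0.02 (percentile 55.4), against 0.14 (percentile 98.0) with them and Me1 at 0.87. Metal and iron handling had 0.29 (percentile 98.6), with Slc11a1 at 0.92, and percentiles of 95.2 without those cells and 96.2 without cluster 12.

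As measured, the remaining lists lay within the middle 95% of random lists between the doses. Inflammatory cytokines (5 of 17 members at least 1.5-fold higher and 1 lower, Cxcl3 at 2.11 and Cxcl2 at 1.74) had a median of 0.15 (percentile 90.1). The type I interferon list (6 of 19 higher and 2 lower, Rsad2 at 3.74, Ifit1 at 3.65 and Cxcl10 at 2.42) had 0.15 (percentile 69.6), and alternative activation (1 of 10 higher and 1 lower, Ccl17 at 1.03 and Chil3 at -0.61) had -0.13 (percentile 11). Class II presentation (3 of 11 higher and 2 lower, Ciita at 1.31 and H2-Oa at -0.83) had 0.12 (percentile 89.1), and matrix and repair (4 of 18 higher, Areg at 1.61 and Spp1 at 0.60) had -0.06 (percentile 25.6). Immediate early genes (Jun at 0.62) had 0.02 (percentile 62.7), p53 targets (3 of 15 higher, Plk2 at 1.27 and Cdkn1a at 0.98) 0.11 (percentile 88.7), glycolysis (Gpi1 at -0.45) -0.07 (percentile 21.1) and nuclear oxidative phosphorylation (Cox5a at 0.57) -0.02 (percentile 59.2). Centred on genes of like transcript length, nuclear oxidative phosphorylation had -0.21 (percentile 0.15), and without cells holding 3 or more G2 and M phase UMIs class II presentation had 0.24 (percentile 98.6) and immediate early genes 0.18 (percentile 97.9).

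Background from other cells was measured in the same alveolar-macrophage-like sums. Haemoglobin genes made 17.7 CPM (16.5 to 18.9) in air, 0 UMIs at 1 ppm and 39.4 CPM (38.2 to 40.8) at 1.5 ppm. Airway epithelial markers made 199, 143 and 131 CPM, and the surfactant gene Sftpc 4.28, 1.18 and 1.15 CPM. The neutrophil gene S100a8 made 9.61, 15.4 and 15.8 CPM and S100a9 0.162, 0.0269 and 1.62 CPM. Ribosomal protein genes made 7.77%, 9.86% and 10.1% of UMIs in air, 1 ppm and 1.5 ppm, and the nuclear RNA Malat1 9225, 8345 and 8893 CPM.

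The labels name no sex of the mice. Y-linked UMIs were found in 94.6%, 94.8% and 92.9% of alveolar-macrophage-like cells of the air, 1 ppm and 1.5 ppm libraries, and Xist, expressed from the inactive X chromosome of females, in 1, 1 and 0 cells.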

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

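The patterns below were noticed in these data, and the bounds of their tests were written after the patterns were seen and before the deciding values were computed, except for the values for single genes without cluster 12, which were chosen after the result for the 4 genes together was seen.

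Some results lay on opposite sides of filtered air at the 2 ozone doses, each dose beyond counting error or beyond the middle 95% of random lists; with 1 library per dose, the difference was not tested. Heat shock had a median log2 ratio of -0.29 at 1 ppm, or -0.15 (percentile 0.11) centred on genes of like transcript length, and 0.79 at 1.5 ppm. LXR targets had 0.11 and -0.48. At 1 ppm alternatives went both ways: -0.025 (percentile 69.9) among cells of 2.5 to 4% mitochondrial UMIs and percentile 96.3 without cluster 12, but 0.21 (percentile 99.97) centred on genes of like span or like transcript length. Colec12 stood at 0.82 and -0.44, Hcst at 0.49 and -0.48, Pltp at 0.11 and -1.15, Lpl at 0.12 and -0.87, and B4galnt1 at 0.10 and -0.88. Stmn1 stood at -0.24 and 1.40, Prc1 at -0.21 and 1.39, and Cenpp at -0.64 and 0.90. Cluster 11, outside every gene comparison, was 3.76% of cells at 1.5 ppm against 0 cells in air; its cells had a median of 2076 UMIs and carried Ccl3 at 4029 CPM, Ccl4 at 4303 CPM and Csf3r, a granulocyte growth factor receptor gene, at 658 CPM.

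Genes with long genomic spans were lower in the ozone libraries. At 1.5 ppm the 20% of genes with the longest spans had a median log2 ratio of -0.27 and the 20% with the shortest 0.33, a gap of -0.60, and at 1 ppm the gap was -0.39. The tables argue against a higher mitochondrial share of the cells (gap -0.50 among cells of 2.5 to 4% mitochondrial UMIs), clusters rich in nuclear RNA (-0.59 without clusters 7 and 18) and depth per cell (-0.52 after thinning) as the main cause. The mitochondrial band lies below the median share in air (4.12%) and above that at 1.5 ppm (2.31%), so it compares unlike parts of these libraries. What stays open is that each library was prepared once, so a difference in how much unspliced or nuclear RNA each preparation held may be a cause, as may ozone itself; neither was tested.

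Mt1, Mt2, Hmox1 and Slc7a11 were lower in both ozone libraries, with a median over the genes of -1.32 for the mean of both log2 ratios. Without cluster 12, a small group of cells rich in their UMIs, the median was -0.77. The mean of both log2 ratios was then -1.53 for Mt1 and Mt2, which argues against this cluster as their cause. It was -0.44 for Hmox1, which leaves the cluster open, and 0.13 for Slc7a11. Slc7a11 and Hmox1 lead cluster 12, so leaving it out removes cells grouped by these very genes. A move toward 0 follows in part by construction, so the cluster stays a candidate explanation for Slc7a11 that this value cannot decide. Blood in the air library is argued against by haemoglobin at 17.7 CPM there and 39.4 CPM at 1.5 ppm, but only for that dose, since the 1 ppm library had 0 UMIs. A difference between pools of mice, or in handling, was not tested and stays open beside an effect of ozone.

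Cell cycle genes were higher at 1.5 ppm. Without the cells in the top 5% of doublet scores the G2 and M phase median was 0.98 against 1.02 with them, and after thinning the share of cells with 3 or more of its UMIs was 2.48 times that of the air library, which argues against doublets of high score and depth as the cause. Doublets of 2 macrophages can escape such scores. The median was 0.57 among cells of 2.5 to 4% mitochondrial UMIs. That band lies below the median share of macrophage-like cells in air (4.12%) and above that at 1.5 ppm (2.31%). It also lies above the median shares of clusters 6 (2.42%) and 10 (2.48%), whose leading genes include cell cycle genes. The lower median may thus follow in part from the band, and it assigns no part of the pattern to mitochondrial share. A difference between the pools or an effect of ozone may each be a cause and were not told apart by the design.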

How the results depend on the processing

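No paired analysis was possible because each group is 1 library. Cells of 2.5 to 4% mitochondrial UMIs, leaving out clusters or top doublet scores, and centring on gene span or transcript length were chosen after the data were seen. Of 1311 values of named genes under 19 alternatives, 1310 kept their direction, 935 of them scored as the same in size and 375 as moved. Slc7a11 at 1.5 ppm against air was 0.44 without cluster 12. Of 532 values of list medians outside the middle 95% of random lists, 530 kept their direction. The interferon list at 1.5 ppm against air was 0.13 without cycling cells and the LXR list at 1 ppm against air -0.025 among cells of 2.5 to 4% mitochondrial UMIs. Because these genes and lists were picked by size in the same libraries, a kept direction is a weak check. The alveolar-macrophage-like share with the stricter filter was 96.7% in air, 97.6% at 1 ppm and 92.8% at 1.5 ppm, and the neutrophil-like share at 1.5 ppm 0.918%; clustered alone, the air library had 0% neutrophil-like cells. Counts of genes past the size rule, 8, 74 and 57 for 1 ppm against air, 1.5 ppm against air and 1.5 ppm against 1 ppm, became 5, 43 and 29 without cycling cells, 22, 181 and 206 with minimums of 10 CPM and 30 UMIs, 47, 474 and 239 at 1.5-fold and 2, 11 and 7 at 3-fold; for the minimums and folds this follows by construction. Without cluster 12 the first was 4. Genes lower at both doses, 4 as measured, were 2 without cluster 12, without cycling cells, after thinning and by mean CPM per cell, 3 by either scaling factor or like transcript length, and 5 with the stricter filter. Centred on transcript length, the split of higher and lower genes was 3 and 4 for 1 ppm against air (2 and 6 as measured) and 46 and 10 for 1.5 ppm against 1 ppm (53 and 4). Shares of cycling cells in air, 1 ppm and 1.5 ppm were 15.2%, 12.6% and 28.6% at 2 or more UMIs, 6.34%, 6.04% and 18.7% at 5 or more, and 21.1%, 18.4% and 34.2% unthinned, with 1.5 ppm highest each time. Except where a rule's construction shows it, the cause was not tested. Of 66 counts in all, 53 stayed within 1.5 times of the value as measured. Depth limits single genes little, at 37212824 UMIs or more per library in alveolar-macrophage-like cells, but limits every other named class, which had under 100 cells.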

Other observations

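Some differences held within most of the 10 alveolar-macrophage-like clusters that had at least 50 cells in each library, although genes that differ also helped to define the clusters. The matrix gene Fn1 was higher than in air in 10 of 10 clusters at either dose, with log2 ratios from 0.30 to 1.37 at 1 ppm and from 0.19 to 1.36 at 1.5 ppm. Spp1 was higher in 10 of 10 clusters at 1.5 ppm (0.18 to 1.68) and in 9 of 10 at 1 ppm, and Car4 in 10 of 10 at 1 ppm and 9 of 10 at 1.5 ppm. The heat shock list was higher in 10 of 10 clusters at 1.5 ppm (0.53 to 0.98) and lower in 9 of 10 at 1 ppm. Others were uneven. Cholesterol synthesis was higher in 7 of 10 clusters at 1 ppm (-0.54 to 0.59) and in 8 of 10 at 1.5 ppm (-0.64 to 1.20), and in cluster 1, which held 1400 of the 5662 cells at 1.5 ppm, it was 0.13 against 0.83 over all clusters. G2 and M phase was higher in 8 of 10 at 1.5 ppm and lower in 10 of 10 at 1 ppm. The 2 lower at 1.5 ppm were clusters whose leading genes include cell cycle genes. They were cluster 6 (-0.40), with H1f5, H2ac24 and Top2a, and cluster 10 (-0.29), with Ube2c and Cenpf. LXR targets were higher in 10 of 10 at 1 ppm (0.014 to 0.415) and lower in 9 of 10 at 1.5 ppm, with 0.32 in cluster 1. Slc7a11 was lower in 9 of 10 at 1 ppm and in 5 of 10 at 1.5 ppm.

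Per cell, after thinning to 5000 UMIs, the heat shock list had a median of 15 UMIs in air, 13 at 1 ppm and 26 at 1.5 ppm; the 10th percentile was 7, 7 and 14 UMIs. For cholesterol synthesis the 90th percentile was 7, 10 and 14 UMIs and the median 2, 2 and 3. Mt2 had a UMI in 26.1% of thinned cells in air (24.6 to 27.6%), 9.54% at 1 ppm (8.31 to 10.9%) and 9.76% at 1.5 ppm (8.98 to 10.6%).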
